A study of Homo sapiens with 6 samples.

How the data were processed

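RNA was measured on Affymetrix arrays in HaCaT keratinocytes infected with lentivirus, 3 arrays for the empty GV308 vector and 3 for GJB2-D66H. Per the labels, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised. The chip type, the RMA and limma versions and the rule behind the authors' filter are not given in the sources used here. The deposited values are log2 expression values, 1 per probe set and array, and RMA is the method named per the submitters' processing notes; RMA corrects background, makes the arrays' distributions equal and combines the probes of a set. Equal distributions hide any change in the total amount of RNA, so each change is relative to the other genes. The authors' deposited table also holds a log2 fold change, a fold (ratio) and a p-value with its FDR per probe set, and limma is named per the submitters' processing notes. The difference of the group means computed here equalled the deposited log2 fold change for all 39254 probe sets, within 1e-09. The values of single arrays were not compared. The same table has 6 further per-array columns with codes that match no label, which were not used. No detection call or background flag was used, so dim probe sets have values but no statement of presence. The 10 background probe sets, whose means ran from 4.07 to 10.51 in the empty vector arrays, had a median of 5.97 there and 5.99 in D66H. Their means rose steadily with the GC number in their names, from GC16 to GC25. The median is thus a single cut, not matched to the GC content of a gene's own probes, and bounds hold only under it. A gene below it may still lie above the background of its own probes, and the reverse. Where a gene's mean in one group lay below the mean of the arrays' background medians, its fold is given as a lower bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the background median and the gene's own value. This was added after the values were seen, and no fold is given where both groups lay below.

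Of the 39254 probe sets, 73 were controls, 37444 named 1 gene, 1547 named several and 190 named none. Symbols were updated through the Entrez Gene ID with a RefSeq gene table (assembly GRCh38.p14, used for names alone), which matched 37368 probe sets, and 76 kept the symbol of the file. No coordinates are given because the array's build is not named. Each of the 15851 genes was represented by the single-gene probe set with the highest mean over all 6 arrays, with no filter on dim probe sets. Of 9702 genes with several probe sets, 451 had probe sets past the threshold in opposite directions. Probe sets ending in _s_at or _x_at can bind related transcripts, so values of near-identical genes such as HLA genes are uncertain.

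Groups were compared with limma (version 3.58.1, R 4.3.3), lmFit and eBayes on the deposited log2 values of all 6 arrays, with no covariate, as a two-sided moderated test with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Genes were called higher or lower with no minimum fold. With 3 arrays per group the precision is limited by their number, and the median SD within groups was 0.0511. Gene lists (30 lists, 920 memberships, 843 of them measured) were fixed before the data were examined: cornified envelope and terminal differentiation; suprabasal keratins; basal keratinocyte and hemidesmosome; wound and hyperproliferation; connexins; cell junctions; epidermal lipids; cholesterol; mitosis; DNA replication; p53; apoptosis; unfolded protein response; ATF4; interferon; NF-kB; hypoxia; NRF2; epithelial-mesenchymal transition; TGF-beta and YAP; EGFR; Notch; WNT; heat shock; oxidative phosphorylation; ribosomal proteins; ion channels; and markers of fibroblasts, melanocytes, and blood and endothelial cells. Some genes sit in more than 1 list. Each list was tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry, adjusted over the 30 lists. Gene ontology terms came from the annotation in the authors' deposited table, with 15 to 300 tested genes per term (1714 terms), and were tested with camera in the same way. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

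The rule for named genes, also set before the data were examined, took GJB2, loricrin and FLG, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen: members behind small counts in the lists, the members of the interferon list that did not pass, KRT1, KRT2, KRT10, PECAM1, COL1A1 and COL1A2. Some genes that the rule takes are not reported here. The fit was tested on simulated data of 15851 genes, 50 of them changed at each size: it recovered 76% of those with a log2 change of 0.3, 98% at 0.6 and 100% at 1 and 2, and 6.03% of its calls were unchanged genes. The simulated noise was independent between genes and few genes were changed, unlike in the data, so these rates may not hold there. The alternatives were a block for the replicate number, each array left out in turn, quantile normalization again, median centring, eBayes with a trend and robust variances, array weights, leaving out the dimmest 50% or 25% of genes, the mean of a gene's probe sets, every probe set on its own, and a minimum fold of 1.5 or 2.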

Results

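The arrays measured RNA in HaCaT cells, a spontaneously immortalised line of human epidermal keratinocytes, after infection with lentivirus. In 3 arrays the virus carried the empty GV308 vector, and in 3 it carried GJB2 with the substitution p.Asp66His (D66H). GJB2 encodes connexin 26, a gap junction subunit. The deposited RMA values are on the log2 scale, with a median between 7.14 and 7.16 on each array. Array data give no read depth, so the number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, and p-values then measure only the spread between these arrays, which may be technical. All changes are D66H minus empty vector, with the limma p adjusted by Benjamini-Hochberg.

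The first question was whether the transgene was seen and how filaggrin and loricrin, the differentiation transcripts named in the study design, stood. GJB2 (Entrez Gene 2706, probe set 11748025_s_at) rose from 5.60 ± 0.14 (SD, n = 3) in the empty vector arrays to 10.94 ± 0.03 (SD, n = 3) in the D66H arrays, an at least 31.3-fold rise (measured log2 change 5.34, SE 0.07, limma adjusted p = 4.10e-07). Filaggrin (FLG, probe set 11741116_at), which bundles keratin filaments in the upper epidermis, fell from 6.51 ± 0.06 to 5.68 ± 0.14 (SD, n = 3 each), at least 1.44-fold lower (measured log2 change -0.83, SE 0.08, limma adjusted p = 0.000233). Loricrin has no probe set among those analysed here. The other two GJB2 probe sets did not show the rise of the first. Probe set 11727084_at went from 4.30 ± 0.10 to 4.59 ± 0.17 (SD, n = 3 each; log2 change 0.29, adjusted p = 0.0433 over all probe sets), and 11727085_s_at from 5.30 ± 0.02 to 5.35 ± 0.17 (log2 change 0.04, adjusted p = 0.697). All 3 GJB2 probe sets lay below 5.97, the median of the 10 background probe sets, in the empty vector arrays, and averaging the 3 GJB2 probe sets gave a log2 change of 1.89. The construct carries the mutant coding sequence, so the probe set value does not part the mutant RNA from the cells' own.

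**Figure D1:**
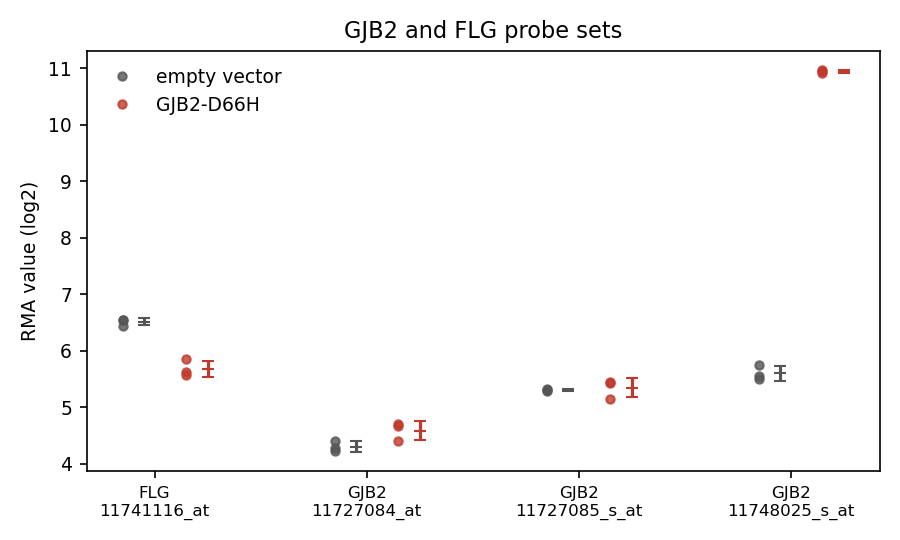
RMA values (log2) of the 3 GJB2 probe sets and the FLG probe set on each array, with empty vector and D66H arrays as separate points and the group means with their SD. GJB2 probe set 11748025_s_at rose from 5.60 to 10.94, the group means of the other two lay between 4.30 and 5.35, and FLG fell from 6.51 to 5.68.

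The main comparison asked which genes differed between D66H and empty vector cells. With GJB2, the 12 genes with the largest measured rise in log2 included MMP13, a collagenase (12.5-fold), SCGB1A1 (6.17-fold) and S100A9 (5.79-fold). The others lay below the background median in the empty vector arrays, so only a bound against that median is given for their rise. It was at least 6.90-fold for the mucin MUC16, 6.05-fold for DCN, the matrix proteoglycan decorin, 5.83-fold for the guanylate-binding protein GBP2 and 5.52-fold for the tryptophan-degrading enzyme IDO1. For the GABA receptor subunit GABRP it was at least 4.41-fold, for the class II antigen HLA-DRA 3.77-fold, for PIGR 3.61-fold and for the small heat shock protein HSPB3 2.07-fold. Among the 12 genes with the largest measured fall were CPA4 (5.03-fold lower), HMGCS1 of cholesterol synthesis (4.66-fold), the AP-1 subunit FOSL1 (4.26-fold), NRG1 (4.22-fold) and ALDOC (3.87-fold). Others fell to below the background median in D66H. C4BPB, a chain of the complement regulator C4b-binding protein, was at least 7.74-fold lower, the neuropeptide precursor GAL 2.89-fold, the chemokine CCL26 2.42-fold, MFAP5 2.39-fold, ANXA10 1.83-fold and COL13A1 1.57-fold. Bounds give no order among these genes. The rule that chose these 23 genes required that they pass the threshold. It also required all 3 arrays of one group to lie beyond all 3 of the other. Their SE of the log2 change lay between 0.0278 and 0.106 and their limma adjusted p between 2.01e-07 and 1.90e-05.

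**Figure D2:**
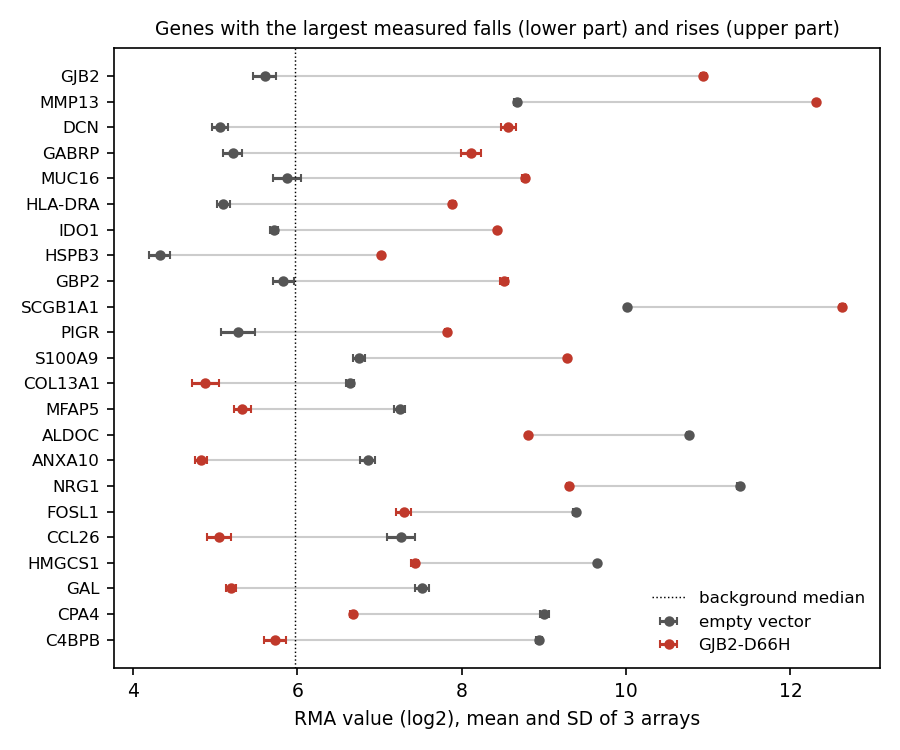
Mean RMA value (log2, horizontal axis) with its SD over 3 arrays for the 12 genes with the largest measured rises and 11 of the 12 with the largest measured falls, empty vector in grey and D66H in red, joined by a line, and a dotted line at the background median of 5.97. GJB2 rose from 5.60 to 10.94 and C4BPB fell from 8.94 to 5.73, each from or to a mean below that line.

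Of 15851 genes tested, 7801 (49.2%) passed an adjusted p of 0.05 in limma, 3934 higher and 3867 lower in D66H. Most changes were small: the median size on the log2 scale was 0.288 among those that passed, 760 genes rose and 414 fell by at least 1.5-fold, and 242 rose and 81 fell by at least 2-fold. Of the genes that passed, 673 lay below the background median in both groups, 164 in the empty vector arrays alone and 122 in the D66H arrays alone. The 2 groups did not overlap for 58.1% of all genes, where chance gives 10% with 3 arrays against 3. The first principal component, with 85.2% of the variance, parted the groups, and Pearson correlations across genes were 0.9986 to 0.9988 within groups and 0.9887 to 0.9891 between them (genes are not independent replicates). The authors' deposited table lists 20035 probe sets with an FDR under 0.05, of which 2786 also reached 1.5-fold, 1682 higher and 1104 lower. These are counts of probe sets, not of genes. With every probe set tested on its own, limma here called 18682. The authors' p-values were thus not reproduced, and the reason was not tested. Measures of RNA and labelling moved with the groups, beside every gene group that follows. The 5′ minus 3′ difference of the ACTB control probe sets was -0.90 ± 0.03 in empty vector and -1.32 ± 0.02 in D66H (log2, SD, n = 3 each), while that of GAPDH was 0.034 ± 0.0135 and 0.0068 ± 0.0022. Of 24 poly-A spike-in probe sets 20 were lower in D66H (median log2 change -0.23), as were 5 of 6 ribosomal RNA probe sets (median -0.78) and 4 of 18 hybridization spike-ins (median -0.07). The ACTB (median -0.40) and GAPDH (median -0.13) control probe sets were lower too, 3 of 3 each, under every scaling tried.

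Interferon-stimulated genes rose almost throughout. Of 39 measured, 37 rose and 0 fell, with the same counts adjusted over the list alone, and the median log2 change was 0.67 (camera adjusted p = 1.53e-16; adjusted p = 0.0222 with an estimated correlation). IFI27 rose by 2.23 on the log2 scale, IRF9, a subunit of the ISGF3 transcription factor, by 1.10, the antiviral TRIM22 by 1.07 and SAMD9 by 0.96. OAS3 (log2 change -0.17, adjusted p = 0.375) and IFNL1 (0.08, adjusted p = 0.269) did not pass. Among gene ontology terms that rose, those with the smallest p came next. In type I interferon signaling 28 of 33 genes rose and 1 fell (camera adjusted p = 7.59e-10), in interferon-gamma-mediated signaling 18 of 26 rose and 2 fell (8.18e-06), and in the lumenal side of the endoplasmic reticulum membrane, a term that holds many HLA genes, 19 of 24 rose and 2 fell (1.58e-05). For all 3 terms, adjusted p = 0.461 with an estimated correlation. NF-kB targets and inflammatory cytokines did not pass in camera, with 9 of 31 rising and 9 falling (9 and 12 adjusted over the list alone; camera adjusted p = 0.611). Within it the interleukins IL1A (log2 change -1.32) and IL1B (-1.11) fell, while TNFAIP2 (0.82) and the NF-kB inhibitor NFKBIA (0.58) rose.

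Sterol synthesis genes fell. Of 24 cholesterol and SREBP2 targets, 22 fell and 2 rose, with the same counts adjusted over the list alone (median log2 change -0.90, camera adjusted p = 6.76e-11; adjusted p = 0.0222 with an estimated correlation). HMGCS1 fell by 2.22 on the log2 scale, INSIG1, which retains SREBP in the endoplasmic reticulum, by 1.71, squalene epoxidase (SQLE) by 1.41 and FDPS by 1.06. The 2 that rose, PMVK (0.30) and TM7SF2 (0.29), were named after the values were seen.

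DNA replication genes fell as well, 32 of 34 with 0 rising, or 33 adjusted over the list alone (median log2 change -0.43, camera adjusted p = 3.14e-13; adjusted p = 0.0222 with an estimated correlation). The origin-licensing factor CDC6 fell by 0.96 on the log2 scale, GINS2 by 0.80, the helicase subunit MCM6 by 0.73 and GINS4 by 0.62. Of 29 mitosis and proliferation genes, 24 fell and 0 rose, with the same counts adjusted over the list alone (median -0.19, camera adjusted p = 4.13e-07; adjusted p = 0.106 with an estimated correlation). Cyclin A2 (CCNA2) fell by 0.52, AURKA by 0.45, cyclin B1 (CCNB1) by 0.41 and CDC20 by 0.33. Of 1714 gene ontology terms, 17 were higher and 121 lower in camera. Among the lower ones, the G1/S transition had 49 of 65 genes falling and 2 rising (adjusted p = 6.84e-09), mitochondrial translational elongation 58 of 85 and 0 (9.23e-09), and rRNA processing 77 of 113 and 10 (2.29e-07). With an estimated correlation camera called 0 of the 1714 terms, the smallest being adjusted p = 0.461 with an estimated correlation, and 173 terms had an unadjusted p under 0.05.

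Keratinocyte lists rose in part. Of 16 genes for suprabasal keratins and spinous differentiation, 10 rose and 2 fell (median log2 change 0.39, camera adjusted p = 0.00915; adjusted p = 0.116 with an estimated correlation). KRT80 (-0.59) and MAF (-0.22) were those that fell, and 3 of those that rose, KRT1 (1.18) among them, lay below the background median in both groups. The mucosal keratins KRT4 (2.05) and KRT13 (1.18) rose with the transcription factors KLF4 (1.15) and GRHL3 (1.04). The keratins KRT10 (0.02, limma adjusted p = 0.616) and KRT2 (0.007, limma adjusted p = 0.958) did not pass. Of 20 basal keratinocyte and hemidesmosome genes, 15 rose and 1, DST (-0.13), fell (median 0.27, camera adjusted p = 3.27e-05; adjusted p = 0.0521 with an estimated correlation). KRT15 rose by 0.89, COL7A1, the anchoring fibril collagen, by 0.83, LAMB3 by 0.75 and ITGA3 by 0.48. Of 21 wound and hyperproliferation genes, 14 rose and 3 fell, or 15 and 4 adjusted over the list alone (median 0.34, camera adjusted p = 0.000342; adjusted p = 0.0548 with an estimated correlation). S100A9 (2.53), SERPINB3 (2.49), S100A7 (2.25) and the protease inhibitor SLPI (2.02) were among those that rose, and FABP5 (-1.04), AKR1B10 (-0.40) and DEFB4A (-0.35) fell. Of the 14 that rose, 1 lay below the background median in both groups and 3 in the empty vector arrays alone. None of these was S100A9, SERPINB3, S100A7 or SLPI. Of 37 cornified envelope and terminal differentiation genes, 11 rose and 3 fell (median 0.05, camera adjusted p = 0.0980), and the list did not pass. Involucrin (IVL) rose by 1.83, transglutaminase 1 (TGM1) by 1.38, LY6D by 1.17 and SCEL by 0.67, while FLG (-0.83), DMKN (-0.40) and SPRR2G (-0.23) fell. The cornified list did pass with the dimmest 50% of genes left out (adjusted p = 0.00493), with the mean of a gene's probe sets (0.0369) and without D66H replicate 3 (0.0404). For the suprabasal, basal and cornified lists the counts adjusted over the list alone were the same.

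Of 26 desmosome, adherens and tight junction genes, 16 rose and 3 fell, with the same counts adjusted over the list alone (median log2 change 0.23, camera adjusted p = 0.00182; adjusted p = 0.126 with an estimated correlation). NECTIN4 rose by 1.46, desmoglein 3 (DSG3) by 0.88, PERP by 0.68 and plakophilin 1 (PKP1) by 0.55, although the 3 probe sets of PKP1 ranged from -0.20 to 0.55. Those that fell were PKP2 (-0.36), TJP1 (-0.28) and CTNNB1 (-0.21). Among 17 connexins and pannexins, 5 rose and 6 fell, also over the list alone, and the list did not pass (camera adjusted p = 0.843). Its median log2 change was -0.02, while its mean was 0.26 and the test pointed up. With the transgene GJB2 left out, a choice made after seeing the data, the mean was -0.05 and camera pointed down (adjusted p = 0.794; fry adjusted p = 0.173). Apart from GJB2, those that rose included GJA5 (0.60) and GJB5 (0.41), whereas connexin 43 (GJA1) fell by 1.20, 2.30-fold lower, and GJC1 fell by 0.60. Of 27 Notch pathway genes, 12 rose and 2 fell, or 13 and 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.0117; adjusted p = 0.348 with an estimated correlation). HES2 rose by 1.44, NOTCH1 by 0.88, HES1 by 0.59 and DTX3L by 0.51, and LFNG (-0.21) and RBPJ (-0.17) fell. Of 24 epidermal lipid and ceramide genes, 7 rose and 5 fell, also over the list alone (camera adjusted p = 0.843). Its median and mean were both -0.01 while the test pointed up. The elongase ELOVL6 fell by 0.94, as did ELOVL4 (-0.50), ABHD5 (-0.38), UGCG (-0.25) and ELOVL1 (-0.09), and NIPAL4 rose by 0.59.

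**Figure D3:**
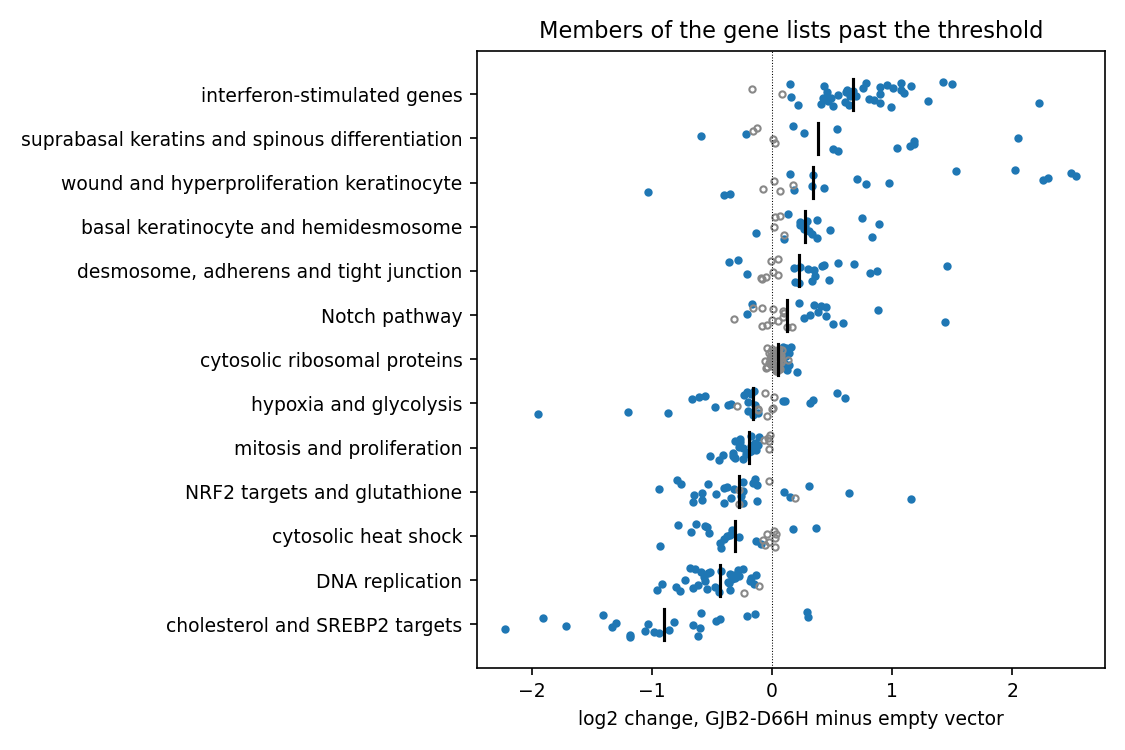
Log2 change (D66H minus empty vector, horizontal axis) of each measured member of the 13 gene lists that passed in camera, with filled points for genes past the threshold, open points for the others and a black bar at the list's median. Interferon-stimulated genes had a median of 0.67, and cholesterol and SREBP2 targets had a median of -0.90.

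Stress and metabolic lists that passed in camera were the following. Of 31 NRF2 targets and glutathione genes, 22 fell and 5 rose, or 24 and 6 adjusted over the list alone (median log2 change -0.27, camera adjusted p = 0.000131; adjusted p = 0.0521 with an estimated correlation). ME1 fell by 0.94, thioredoxin reductase TXNRD1 by 0.79 and the cystine transporter SLC7A11 by 0.76, while the aldehyde dehydrogenase ALDH3A1 rose by 1.16, followed by GPX2 (0.64), PIR (0.31), FTH1 (0.15) and GPX4 (0.10). Of 26 cytosolic heat shock genes, 16 fell and 2 rose, or 17 and 2 adjusted over the list alone (median -0.31, camera adjusted p = 0.000271; adjusted p = 0.0548 with an estimated correlation). CHORDC1 fell by 0.94, HSPH1 by 0.78, and HSPE1 and HSPD1, which are mitochondrial chaperonins, by 0.56 and 0.54, while the small heat shock proteins HSPB8 (0.36) and HSPB1 (0.17) rose. Of 32 hypoxia and glycolysis genes, 18 fell and 6 rose, or 20 and 6 adjusted over the list alone (median -0.15, camera adjusted p = 0.00394; adjusted p = 0.123 with an estimated correlation). ALDOC fell by 1.95, BNIP3 by 1.20 and PFKP by 0.55, while PFKFB3 rose by 0.60, and the list no longer passed with the dimmest 50% of genes left out (adjusted p = 0.0895). Of 51 cytosolic ribosomal protein genes, 12 rose and 0 fell, or 10 and 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.0340; adjusted p = 0.348 with an estimated correlation). RPL10A rose by 0.21 and RPS19 by 0.14. That call was lost with repeated quantile normalization (adjusted p = 0.392, 9 rising and 1 falling), with median centring (0.0862), with the dimmest 50% of genes left out (0.0905, 24 rising and 1 falling) and with the mean of a gene's probe sets (0.115, 12 rising and 3 falling).

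Other stress and energy lists did not pass in camera. Of 28 genes of the unfolded protein response in the endoplasmic reticulum, 12 fell and 4 rose, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.0980), among them SDF2L1 (-0.87), calreticulin (CALR, -0.71), the chaperone HSPA5 (-0.67) and MANF (-0.47). DNAJB9 (0.30), HERPUD1 (0.18), CREB3L2 (0.13) and SYVN1 (0.13) rose. Of 29 ATF4 and CHOP targets, 9 rose and 11 fell, also over the list alone (camera adjusted p = 0.590), with WARS1 (0.76) and PHGDH (0.60) rising and STC2 (-0.87) falling. Of 45 oxidative phosphorylation genes, 16 fell and 2 rose, also over the list alone (camera adjusted p = 0.108), and NDUFS1 of complex I fell by 0.38 and NDUFB8 by 0.24, while NDUFB10 (0.19) and NDUFB5 (0.12) rose.

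Apoptosis was part of the study's design. Of 42 apoptosis genes, 19 rose and 11 fell, or 20 and 11 adjusted over the list alone, and the list did not pass (median log2 change 0.10, camera adjusted p = 0.258). The death ligand TNFSF10, which is also induced by interferon, rose by 1.77, while the death receptor TNFRSF10A fell by 0.49 and DFFA by 0.51. Of 29 p53 targets, 10 rose and 12 fell, also over the list alone (camera adjusted p = 0.822), with TP53INP1 (1.90), BTG2 (1.23) and DDB2 (0.65) rising and GADD45A (-0.77) falling.

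In the growth factor and matrix lists genes went both ways, and none passed in camera. Of 34 EGFR ligands and immediate early genes, 13 rose and 15 fell, or 13 and 16 adjusted over the list alone (camera adjusted p = 0.546), with FOSL1 (-2.09), the phosphatase DUSP4 (-1.58), ETV4 (-1.12) and IER3 (-1.10) falling. Of 28 TGF-beta and YAP targets, 8 rose and 11 fell, also over the list alone (camera adjusted p = 0.590), with ID2 (1.44) and ID3 (0.65) rising and CCN1 (-1.03) and AXL (-0.85) falling. Of 33 genes for epithelial-mesenchymal transition and extracellular matrix, 8 rose and 11 fell, also over the list alone (camera adjusted p = 0.773), with a median of -0.04 and camera pointing down but a mean of 0.08 and fry pointing up. MMP13 (3.64) and MMP7 (1.33) rose, and N-cadherin (CDH2, -1.22) and COL4A1 (-1.06) fell. Of 30 WNT pathway genes, 5 rose and 10 fell, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.265), with WNT4 (1.13), WNT10A (0.57), TCF7L2 (0.23), FZD6 (0.18) and FZD5 (0.15) rising and DKK1 (-0.75) falling. Of 32 ion channel and calcium handling genes, 8 rose and 9 fell, also over the list alone (camera adjusted p = 0.822), with SCNN1A (0.53) and TRPV6 (0.46) rising and ATP2B1 (-0.61) falling.

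Lists of markers of other cell types did not pass in camera. Of 13 blood and endothelial cell markers, 5 rose and 0 fell (camera adjusted p = 0.194), namely VWF (1.27), CDH5 (0.99), CD68 (0.65), CD14 (0.45) and KDR (0.29), while PECAM1 stood at -0.05 (adjusted p = 0.715). Of 10 fibroblast markers, 2 rose and 2 fell (camera adjusted p = 0.771). DCN (3.51) and FBLN1 (0.98) rose and MFAP5 (-1.91) and COL3A1 (-0.17, adjusted p = 0.0250) fell, while COL1A1 (0.09, adjusted p = 0.476) and COL1A2 (0.11, adjusted p = 0.180) did not pass. Of 5 melanocyte markers, 1 rose and 2 fell (camera adjusted p = 0.754), with MITF at -0.51, TYR at -0.24 and PMEL at 0.14. The calls of COL3A1, TYR and PMEL were each lost when single arrays were left out. The counts adjusted over the list alone were the same for these 3 lists.

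Over the 30 lists, camera called 13, of which 7 were higher and 6 lower, and 3 of them held with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 29 of the 30, the connexins with GJB2 among them. For the 118 genes that the rule for named genes took from the lists by their small p, the SE of the log2 change lay between 0.0245 and 0.130 and the limma adjusted p between 2.01e-07 and 0.0250. Of the genes named from the lists, GJA5, KRT1, KRT2, MAF, SPRR2G, CD14, KDR, TYR, COL1A1, COL1A2, PECAM1, OAS3 and IFNL1 lay below the background median in both groups, and GJB2, DCN, VWF, TP53INP1, FLG, MFAP5, DEFB4A and ELOVL4 in one, so their log2 changes are values as measured. No group carried normal GJB2, so what the D66H change adds to a higher GJB2 level was not compared here.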

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

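The tests on the array controls in this part were chosen after the results were seen, while the splits of the arrays were planned before the data were examined. Probe sets outside the gene comparison also carried differences between D66H and the empty vector arrays. Of 1737 probe sets that name several genes or none, 400 were higher in D66H and 366 lower (limma, Benjamini-Hochberg over all probe sets). Of 73 control probe sets, 2 were higher and 35 were lower.

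That 7801 of 15851 genes passed the threshold may come in part from hybridization, staining or labelling that differed between the groups. The largest shifts on the log2 scale were -0.157 among 18 hybridization spike-in probe sets, -0.83 among 24 poly-A spike-ins and -1.14 among 6 ribosomal RNA probe sets. Of the genes that passed, 84.4% changed by more in size than the first of these and 1216 did not, but genes parted by the size of their own change exclude nothing, so hybridization and staining cannot be told apart from an effect of the insert. Arrays of a group may also repeat one culture, and with a median SD of 0.0511 within groups and no label that names separate cultures this cannot be told apart. An effect of D66H, or of more GJB2 of any sequence, stays open.

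The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold the real split gave 7801 and the highest other 0, so 1 of 10, the real one, gave as many. For gene lists in camera the real split gave 13 and the highest other 14, so 2 splits gave as many, the other one placing empty vector replicates 1 and 3 with D66H replicate 3. With an estimated correlation the real split gave 3 lists and the others 0. For gene ontology terms the real split gave 138 and the highest other 72, so again 1 of 10 gave as many. Every other split mixed arrays of both groups, so the group difference entered the spread within each part. The 0 genes there follow from that difference whatever its cause, and exclude nothing. The mixed splits also kept part of the difference between their parts, so their list and term counts do not measure chance.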

How the results depend on the processing

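GJB2 and FLG kept direction and threshold under every alternative run for them. The count of genes past the threshold, 7801, came to 18682 with every probe set on its own, where more features were tested, and to 1174 and 323 with a fold of at least 1.5 or 2, where the added minimum removes small changes. With an estimated correlation, camera called 3 lists in place of 13. It called 0 gene ontology terms in place of 138 (173 at an unadjusted p under 0.05). The estimate lay below the preset 0.01 for the basal (-0.037), suprabasal (-0.035), wound (-0.021), NRF2 (-0.009) and heat shock (-0.005) lists, which lost the call. For these lists a correlation above the preset was therefore not the reason. It lay above the preset for the other lists that lost the call, up to 0.114 for Notch. The cause was not tested further. The other counts of genes lay between 6228 (dimmest 50% left out) and 8370 (trend and robust variances), and a minimum set by the largest spike-in shift, chosen after seeing the data, left 6585. Which direction held more genes depended on the choice. Against 3934 higher and 3867 lower, the mean of a gene's probe sets gave 3591 and 4116, and median centring 3723 and 4020. Repeated quantile normalization, the dimmest 50% left out and every probe set on its own also gave more lower than higher. The remaining alternatives gave more higher. Leaving out each array in turn gave 6973 to 7214 genes, 12 to 13 lists, 111 to 151 terms, a GJB2 log2 change of 5.29 to 5.42 and an FLG log2 change of -0.91 to -0.78. With the replicate number as a block, the fit gave 7100 genes, 12 lists, 123 terms, 5.34 for GJB2 and -0.83 for FLG. Between the groups, the highest correlation of deviations was 0.158, for empty vector replicate 1 and D66H replicate 3. No pairing by number was seen, since same-numbered arrays' deviations correlated at -0.082, 0.039 and -0.083, and no array correlated best with its own number. With 3 arrays per group this cannot exclude that same-numbered arrays were handled together, and the labels do not say. The ribosomal protein list (adjusted p 0.0340, and 0.0503 to 0.392 over the alternatives that ended its call) was also lost without empty vector replicate 2 (0.0657), without D66H replicate 3 (0.0632) and under the block (0.0503), and the cause was not tested. Of 1831 values for 133 other named genes, 1817 kept direction and threshold, 0 reversed and 14 lost the threshold, all of COL3A1, TYR and PMEL. COL3A1 lost it without empty vector replicates 2 or 3 or D66H replicates 1 or 3, TYR without empty vector replicates 1 or 2 or D66H replicates 2 or 3, and PMEL without empty vector replicates 2 or 3 or D66H replicates 2 or 3, under the block and with trend and robust variances. The median log2 change of all genes was -0.0066 as deposited, -0.0043 after quantile normalization and -0.0169 after median centring. The authors' filtered table was not run as an alternative, since its per-array columns match no label. Signal near the background probe sets (median 5.97, a cut not matched to each gene's probes) limits what dim probe sets can show.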

Other observations

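The 5 gene lists of this part were chosen after the values were seen, as were all its tests except that on the interferon genes, so their counts are not independent evidence of direction. Their p were adjusted over all 35 lists, the 30 fixed earlier and these 5. Antigen presentation genes rose. Of 14 genes for MHC class II and its regulators, 11 rose and 0 fell (median log2 change 1.01, camera adjusted p = 7.54e-05; adjusted p = 0.0483 with an estimated correlation). HLA-DRA rose by at least 1.91 (2.78 as measured), HLA-DRB1 by at least 1.81 (2.17 as measured), HLA-DMA by 1.63 and the invariant chain CD74 by 1.55. CIITA, the transactivator of class II genes, stood at -0.02 (adjusted p = 0.761) and HLA-DPB1 at -0.03 (adjusted p = 0.788). The means of CIITA, 6.19 in empty vector and 6.16 in D66H, lay close to the background median of 5.97, so its probe set may not show a change. Of the 11 that rose, 3 lay below the background median in both groups and 3, HLA-DRA, HLA-DRB1 and HLA-DPA1, in the empty vector arrays alone. Of 18 genes for MHC class I and peptide loading, 16 rose and 0 fell (median 0.58, camera adjusted p = 1.22e-08; adjusted p = 0.0483 with an estimated correlation), with HLA-F at 1.41 and the peptide transporter TAP1 at 0.70. The immunoproteasome subunits PSMB10 (0.77), PSMB9 (0.57) and PSMB8 (0.30) rose. Of 30 other subunits listed for the 26S proteasome, 26 fell and 0 rose (median -0.26, camera adjusted p = 1.78e-09; adjusted p = 0.0675 with an estimated correlation), with PSMD7 at -0.63 and PSMD1 at -0.55. PSMB6 (-0.31) and PSMB7 (-0.16) fell too, whereas PSMB5 (-0.06, limma adjusted p = 0.166) did not pass. A switch between forms of the proteasome was not tested.

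Fatty acid synthesis genes fell beside those of sterol synthesis. Of 17 measured, 13 fell and 1 rose (median log2 change -0.67, camera adjusted p = 9.20e-06; adjusted p = 0.126 with an estimated correlation). LPIN1 fell by 1.59, fatty acid synthase (FASN) by 1.56 and PNPLA3 by 1.13, and the 1 that rose was SREBF1 (0.63), which encodes the SREBP1 regulator of this pathway. Among 25 genes of secretory and mucosal epithelium, 13 rose and 4 fell (median 0.11, camera adjusted p = 0.0173; adjusted p = 0.198 with an estimated correlation). Of those that rose, 2 lay below the background median in both groups and 4, MUC16 among them, in the empty vector arrays alone. MUC16 rose by at least 2.79 (2.89 as measured), SCGB1A1 by 2.63, AGR2 by 2.44 and MUC4 by 1.30, while the simple-epithelium keratins KRT18 (-0.74), KRT8 (-0.50) and KRT7 (-0.22) and the tetraspanin TSPAN8 (-1.14) fell and KRT19 rose by 0.11.

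The rise of interferon-stimulated genes may be technical, biological or both. A hybridization shift no larger than that of the spike-ins is argued against for this list. Its lower quartile was 0.46 on the log2 scale, and the largest shift of a hybridization spike-in was -0.157. The spike-ins do not bound what hybridization did to other probe sets, so a larger effect there was not tested. Labelling stays open too, with poly-A spike-ins at -0.83 to -0.08. The amount of lentivirus or of double-stranded RNA, rather than the insert, cannot be told apart, because no group carried another insert. The 3 interferon genes measured, IFNE (log2 change 0.27, adjusted p = 0.0808), IFNL1 (0.08) and IFNA14 (-0.01), lay below the background median in both groups, so their changes decide nothing. An effect of the D66H insert stays open.

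That 1 of 3 GJB2 probe sets followed the transgene may come from a construct that lacks the sequence the other probe sets target, or from probe sets too dim to report the gene. The larger log2 change of the other two, 0.29 (SE 0.09), only restates the pattern. Low signal decides nothing either: the brighter of the other two stood at 5.30 in the empty vector arrays, and the probe set that rose stood at 5.60 there, also below the background median of 5.97. The positions of the probes are not given in the sources used here, so these explanations cannot be told apart.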
